A study of Mus musculus with 7 samples.

How the data were processed

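Bone marrow cells of wild-type C57Bl/6J mice were sorted by the authors, and amplified RNA was hybridised to 7 Affymetrix Mouse Genome 430 2.0 arrays. Per the labels, the values are log2 expression values that the authors made with Affymetrix Expression Console 1.1 and RMA, which corrects background, normalizes by quantiles and summarises the probes of a probe set before deposit. Which arrays were normalized together is not stated. The deposited table holds 45101 probe sets and no detection calls were used. All 7 columns were used and no 2 were identical. The array medians lay between 6.00 and 6.19. For arrays, no depth applies, and their number limits the precision. The labels do not say whether the replicates come from separate mice or sorts, so each p measures only the spread between these samples.

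Gene symbols came from a probe annotation of 2016. Of the probe sets, 34945 had 1 symbol, 932 had several, 9160 had none and 64 were controls. Of those with 1 symbol 34741 had an Entrez identifier in the gene table of mouse assembly 38 (patch 6), and 0 symbols needed an update. Genome positions are not analysed here. Each of 18193 genes was represented by its probe set with the highest mean over all arrays among probe sets with 1 symbol. A gene was tested if at least 3 arrays lay above their own 40th percentile, which left 13995 genes and set aside 4198.

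Differences were computed as stromal minus endothelial with limma 3.58.1 (lmFit and eBayes, no covariates) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested. Calls required an adjusted p under 0.05 and a log2 difference of at least 1. The 47 gene lists (863 entries, 783 distinct genes, 712 on the array and 626 tested) were tested with limma's camera at a preset correlation of 0.01, two-sided and adjusted over the lists, and with an estimated correlation and fry as alternatives. Members without a matching symbol were sought by synonym, which matched Rpl23 to Mrpl23, a different gene, and Loxl2 to Loxl3, already a member of that list. The lists cover niche, mesenchymal, endothelial and matrix genes, signalling pathways, housekeeping processes and blood lineages. The 3' minus 5' differences of control transcripts were compared with an exact two-sided permutation test.

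The named genes were the sorting antigen genes and a set of niche and endothelial genes, the 12 genes with the largest difference in each direction whose groups did not overlap, and from each list up to 4 members in its main direction and up to 2 in the other. Symbols of unnamed gene models were passed over, which happened 1 time. The rule gave 228 genes, of which 226 were tested and 224 passed the threshold. The lists, the rule, the thresholds and the alternatives below were set before the data were examined. These alternatives were no filter or one at the 60th percentile, the mean of a gene's probe sets, leaving out probe sets with the cross-hybridising suffixes, a second quantile normalization, cyclic loess, centring on ribosomal protein genes, eBayes with trend and robust options, array weights, adjusted p alone, treat, a count per probe set, replicate number as a block, middle in place of 3' control probe sets, and leaving out each array in turn. The hybridisation-control block, the comparison within the 5 arrays of like hybridisation-control level, the fit without stromal 4 and endothelial 2, and the ribosomal list without Mrpl23 were chosen after seeing the data, as were 4 further gene lists. The block and the 5 arrays both compare endothelial 1 alone with the stromal arrays.

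The procedure was tested on simulated data in which 50 genes per size were changed. It recovered 30 of 50 genes at a log2 change of 1.5, 43 at 2, 44 at 3 and 49 at 4. The members of a further list were shifted as well, so the genes called can include them. Of 197 genes called, 13 had been changed in neither way, and the median absolute error of a simulated log2 fold was 0.133. The shifted list passed and an unshifted list had a camera adjusted p of 0.907. Noise was drawn for each gene independently and most genes were left unchanged, unlike in the data. The simulation therefore does not test how the calls hold where genes are correlated.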

Results

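Gene expression was measured on 7 Affymetrix Mouse Genome 430 2.0 arrays, each hybridised with amplified RNA from 1800 to 10000 cells sorted from the bone marrow of wild-type C57Bl/6J mice aged 6 to 12 weeks. Both sorted populations lacked CD45, the pan-leukocyte antigen encoded by Ptprc, and lineage markers. The first population was positive for CD54 (Icam1) and BP1 (Enpep) and negative for CD31 (Pecam1). It carries the label stromal cells and has 4 arrays, called stromal 1 to 4 here. The second was negative for CD54 and positive for CD31. It carries the label endothelial cells and has 3 arrays, called endothelial 1 to 3 here. The comparison asks which genes distinguish these cell populations. Values are the deposited log2 expression values, and differences are given as stromal minus endothelial unless a fold is stated. The mean of the 18 hybridisation control probe sets, which report spiked-in label and not cellular RNA, was 11.33 and 11.37 on endothelial 2 and 3 and 9.51 to 9.75 on the other 5 arrays. This split was set as a block in an added fit, and the 5 arrays of like level were also compared alone. Endothelial 2 and 3 are the only arrays of the high level, so the block absorbs them and both fits compare endothelial 1 alone with the 4 stromal arrays. They are the same single check, which assumes that endothelial 1 varies like the others. For any given probe set they give the same difference, and they part only in residual variance, filter and choice of probe set. The highest values lay between 14.68 and 14.82 and the 40th percentiles between 5.48 and 5.79. Differences from levels near either end are limited by the range of the arrays. No fold is given for a single gene where a population's mean lay below its arrays' 40th percentile. The number of arrays limits the precision of every value.

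The transcripts of the sorting antigens followed the gates for CD54, BP1 and CD31. Enpep was higher on the stromal arrays (12.00 ± 0.19, SD, n = 4, against 5.08 ± 0.74, n = 3), with a limma adjusted p of 1.13e-06. Icam1 was higher there as well (10.50 ± 0.35 against 5.31 ± 0.49, adjusted p = 2.48e-06). Pecam1 was higher on the endothelial arrays (8.41 ± 0.64 against 4.93 ± 0.21, adjusted p = 2.95e-05). For these 3 genes the mean of the lower population lay below its arrays' 40th percentile. Ptprc was 9.18-fold higher on the endothelial arrays (adjusted p = 0.00439), at 8.63 to 10.94 on the 3 endothelial and 4.91 to 7.42 on the 4 stromal arrays, although both populations were sorted as CD45-negative. With the split in hybridisation controls as a block, where endothelial 1 alone stands for its population, the difference in Ptprc was -2.92 and the adjusted p was 0.0597, the highest among the alternatives, whose lowest was 5.83e-04.

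Genes of the reticular niche and of adipocytes were among those most raised on the stromal arrays, and megakaryocyte and platelet genes among those most raised on the arrays labelled endothelial. The 12 genes with the largest difference toward the stromal arrays were Serping1, Errfi1, Ms4a4d, Cdh2, Igfbp5, Adipoq, Lepr, Ogn, Mmp13, Epas1, Cyp1b1 and Lifr, with log2 differences from 9.34 to 8.42. The 12 with the largest difference toward the endothelial arrays were Ctla2b, Clec1b, Ppbp, Rgs18, Alox12, Cracd, Gp1bb, Ctla2a, Gad1, Tesc, Mfsd2b and Mfap3l, from -9.12 to -7.60. In 11 of the former and 7 of the latter the mean of the lower population lay below its arrays' 40th percentile, so the floor of the arrays limits the size and order of these differences. Single arrays also set the order: without stromal 4, Ppbp (-10.11), Clec1b (-9.74) and Tubb1 (-8.35, and not among the 12) move outward. The choice of probe set matters more, and the order is not firm. With the mean of a gene's probe sets 14 of these 24 genes moved by over 1 on the log2 scale, for example Errfi1 from 9.04 to 5.26, Epas1 from 8.54 to 5.02, Cyp1b1 from 8.51 to 5.14 and Gp1bb from -7.91 to -5.49. Within the 5 arrays of like hybridisation-control level, where other probe sets of these genes were chosen, Gad1 fell from -7.86 to -1.32 and Cracd from -8.15 to -1.70. Of the 222 named genes tested both ways, 69 moved by over 1 with the mean of the probe sets, 66 of them to a smaller difference, so the sizes given below hold for the probe set used. Among the endothelial 12, Clec1b encodes the platelet receptor CLEC-2, Ppbp a platelet chemokine, Gp1bb a subunit of the platelet von Willebrand factor receptor and Alox12 the platelet 12-lipoxygenase. Of 13995 genes tested, 4319 were higher on the stromal arrays and 2252 on the endothelial arrays (limma, adjusted p under 0.05 and a log2 difference of at least 1). Over all genes tested, called or not, every array of one population lay above every array of the other in 9569 (68.4%), where chance gives 5.71%. The difference reached 16-fold in 502 genes toward the stromal arrays and in 193 toward the endothelial arrays. These counts include genes whose lower population lay below its arrays' 40th percentile, where the floor limits the size. Of all calls 65.7% were toward the stromal arrays. After a second quantile normalization the counts were 3206 and 3014, a share of 51.5%, and after cyclic loess 3270 and 2388, a share of 57.8%. The median difference over all tested genes was 0.19 as deposited, -0.13 after the second quantile normalization and -0.02 after cyclic loess, and the differences below lie on top of that shift. In the comparison of endothelial 1 alone with the stromal arrays the counts were 4035 and 2236 with the hybridisation-control split as a block and 4979 and 2782 within the 5 arrays. They differ through the residual variance, the filter and the probe sets chosen, and are not separate checks.

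**Figure D1:**
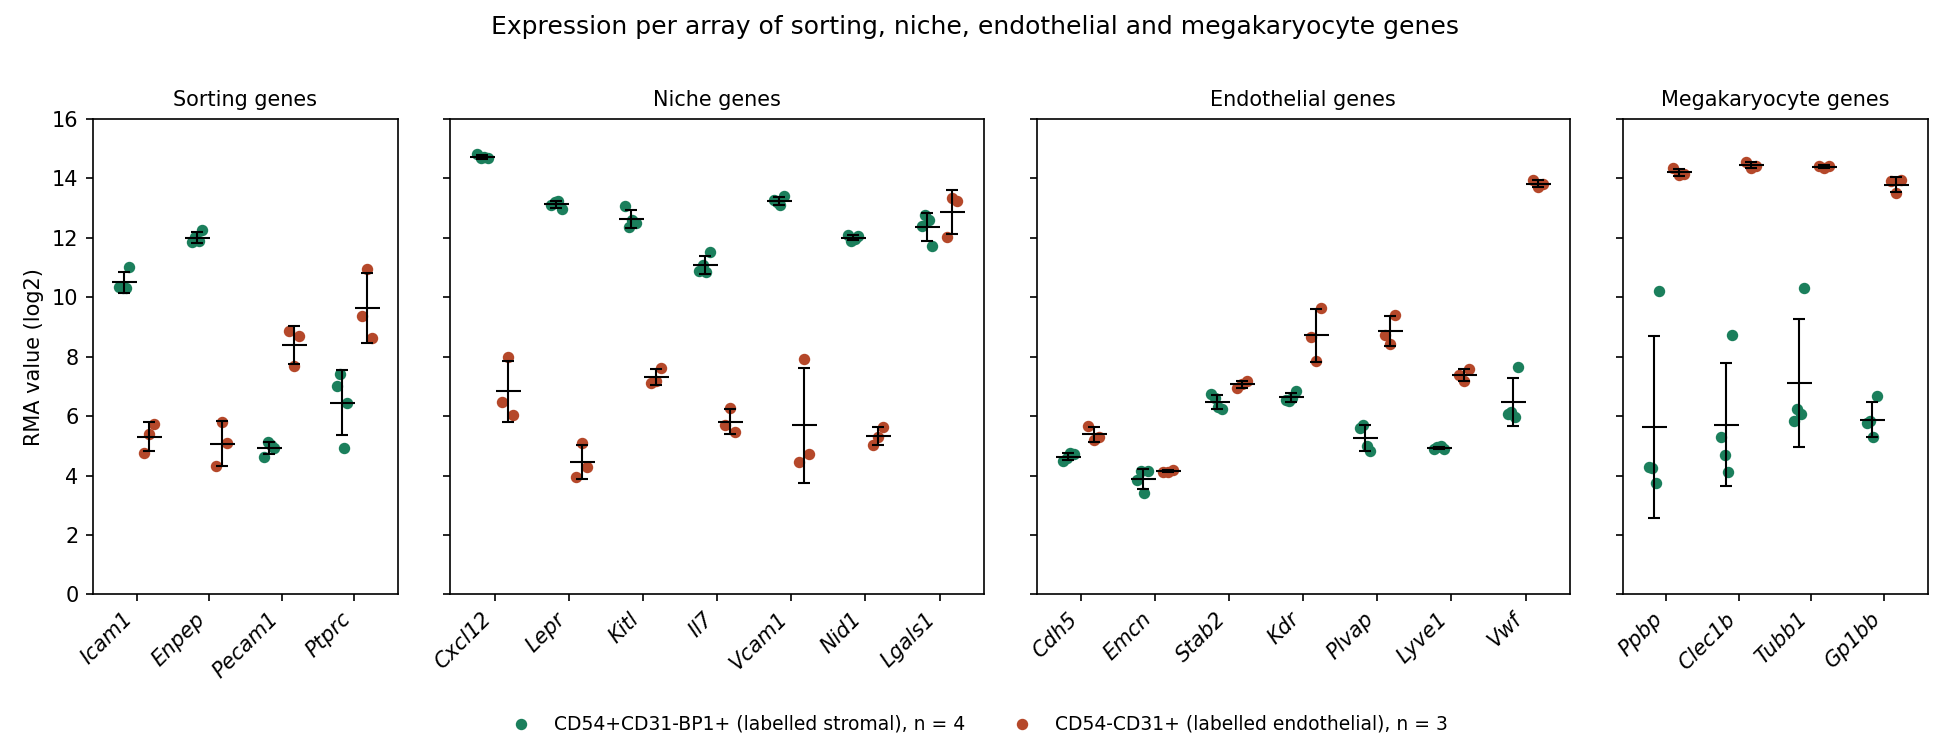
Log2 expression of sorting antigen, niche, endothelial and megakaryocyte genes, with 1 point per array (green, stromal, n = 4; red, endothelial, n = 3) and black marks for the group mean and SD. For each of Ppbp, Clec1b, Tubb1, Gp1bb and Vwf all 3 endothelial arrays lie above all 4 stromal arrays. Stromal 4 lies above the other 3 stromal arrays for each of these genes.

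Genes of the CXCL12-abundant reticular stroma, the perivascular cells that support blood formation, were higher on the stromal arrays in 17 of 18 members tested. Cxcl12, the chemokine that retains haematopoietic cells in the marrow, lay at 14.73 ± 0.06 (n = 4) against 6.84 ± 1.03 (n = 3, adjusted p = 1.97e-06), with its stromal values close to the top of the arrays' range. The transcription factors Ebf3 and Foxc1, which maintain these cells, were higher by 7.14 and 6.81 on the log2 scale. The leptin receptor gene Lepr was higher by 8.67, and by 3.70 to 3.93 when 1 stromal array at a time was left out, because another probe set of the gene then had the highest mean. Igfbp5, at 8.79, fell to 0.96 to 1.11 for the same reason. The list median was 6.97 (camera adjusted p = 1.95e-08, and adjusted p = 0.0818 with an estimated correlation).

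Most listed factors that act on haematopoietic cells were also higher on the stromal arrays. Of 16 haematopoietic niche factors tested, 12 were higher on the stromal arrays, 2 on the endothelial arrays (Jag2 at -1.28 and Tgfb1 at -1.05) and 2 passed neither way (camera adjusted p = 4.67e-04, and adjusted p = 0.0818 with an estimated correlation). Kitl, which encodes stem cell factor, was higher by 5.32 (12.63 ± 0.30 against 7.31 ± 0.28, adjusted p = 6.92e-07), with a range over the alternatives from 4.92 to 9.43, the upper end from another probe set of the gene. Bmp4 was 104-fold higher. The Tgfb1 difference missed the threshold without stromal 2 (-0.92), without endothelial 3 (-0.75) and with the hybridisation-control block or within the 5 arrays (-0.60). Among genes that support B-cell precursors, 9 of 11 were higher on the stromal arrays (adjusted p = 0.00180, and adjusted p = 0.113 with an estimated correlation). Il7, the cytokine that B-cell precursors need, was 38.5-fold higher (11.08 ± 0.30 against 5.81 ± 0.42, adjusted p = 1.35e-06). Nid1, which encodes the basement membrane protein nidogen-1, was higher (12.01 ± 0.10 against 5.33 ± 0.30, adjusted p = 1.77e-07). Vcam1 was higher by 7.56, and by 8.67 without endothelial 2, where it lay at 7.91 against 4.44 and 4.72 on endothelial 1 and 3. Lgals1, which encodes galectin-1, did not pass the test (12.37 ± 0.46 against 12.86 ± 0.73, adjusted p = 0.268).

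Most adipogenic genes, osteogenic genes and mesenchymal transcription factors were higher on the stromal arrays. In the adipogenic list 7 of 8 members tested were higher (adjusted p = 7.23e-04, and adjusted p = 0.128 with an estimated correlation). The array held 11 members, and those below the filter for dim genes are not in this share. Higher members included the adipokine gene Adipoq at 14.35 ± 0.03 against 5.61 ± 0.37 and the lipase gene Lpl at 14.43 ± 0.05 against 7.39 ± 1.61. In the osteogenic list 11 of 13 were higher (adjusted p = 3.06e-04, and adjusted p = 0.152 with an estimated correlation), among them Ibsp, which encodes bone sialoprotein, by 8.31 and Tnfsf11, which encodes the osteoclast factor RANKL, by 7.02. Of 13 mesenchymal transcription factors tested, from 18 on the array, 11 were higher (adjusted p = 2.08e-05, and adjusted p = 0.0818 with an estimated correlation), with Snai2 at 8.32 and Prrx1 at 7.19.

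The lists of matrix genes, metalloproteases, BMP and TGF-beta, Wnt, IGF and MHC class I genes shifted in the same direction, while those of chemokine and VEGF ligands, given further on, did not pass. Of 28 interstitial matrix genes 24 were higher on the stromal arrays and 1 on the endothelial arrays (adjusted p = 1.04e-06, and adjusted p = 0.152 with an estimated correlation). Tnc lay at 13.67 ± 0.10 against 5.67 ± 2.01 (a difference of 9.15 without endothelial 2) and Col6a1 was higher by 7.25, while Thbs1, which encodes a protein stored in platelet granules, stood at -3.37. Of 23 basement membrane genes 15 were higher on the stromal and 3 on the endothelial arrays (adjusted p = 0.00936, and adjusted p = 0.230 with an estimated correlation). Col4a1 and Col4a2, the main chains of type IV collagen, were higher by 6.30 and 5.99, and Col4a5 stood at -1.34, or -0.99 and short of the threshold after cyclic loess. Metalloproteases and their inhibitors were higher in 15 of 20 members (adjusted p = 1.18e-04, and adjusted p = 0.152 with an estimated correlation), with Mmp13 at 8.58. The BMP and TGF-beta list had 18 of 24 members higher on the stromal and 2 on the endothelial arrays (adjusted p = 4.98e-05, and adjusted p = 0.0818 with an estimated correlation). Bmp6, Bmp5 and the BMP antagonist gene Chrdl1 were higher by 7.26, 6.79 and 7.12, while Bmp2 stood at -1.29. In the Wnt list 15 of 21 members were higher (adjusted p = 3.72e-05, and adjusted p = 0.0818 with an estimated correlation). They included the secreted enhancers Rspo2 and Rspo3, at 7.67 and 7.23, and the secreted inhibitors Wif1 and Sfrp4, at 7.05 and 6.33. In the IGF list 7 of 9 were higher (adjusted p = 0.00243, and adjusted p = 0.119 with an estimated correlation), with Igfbp3 at 7.12 and Igfbp7 at 6.66. Antigen presentation by MHC class I had 8 of 11 members higher (adjusted p = 0.0471, and adjusted p = 0.298 with an estimated correlation), led by Tap2 at 3.26 and the class I transactivator gene Nlrc5 at 3.16. The class I call was lost without endothelial 3 (adjusted p = 0.0549), with a filter at the 60th percentile, with the mean of a gene's probe sets and without cross-hybridising probe sets, and its adjusted p over all alternatives lay between 3.32e-04 and 0.298.

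On the arrays labelled endothelial, all 11 megakaryocyte and platelet genes tested were higher, with a list median of -6.95 (camera adjusted p = 1.62e-06, and adjusted p = 0.308 with an estimated correlation). Ppbp stood at 14.21 ± 0.12 (n = 3) against 5.62 ± 3.06 (n = 4, adjusted p = 0.00122) and Tubb1, the platelet form of beta-tubulin, at 14.39 ± 0.05 against 7.11 ± 2.14 (adjusted p = 4.49e-04). The wide stromal spread came from stromal 4, where Ppbp lay at 10.19 and Tubb1 at 10.32. Without it the differences were -10.11 for Ppbp, -8.35 for Tubb1 and -9.74 for Clec1b. Gp1bb stood at -7.91 (adjusted p = 5.27e-07).

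Pan-endothelial genes went several ways. Of 17 tested, 6 were higher on the endothelial arrays, 1 on the stromal arrays and 10 passed neither way. The median was -0.88 (camera adjusted p = 0.00569, and adjusted p = 0.172 with an estimated correlation). Genes below the filter had a median of -0.58, so a list median of this size is open to the same shift. Higher on the endothelial arrays were Vwf, which megakaryocytes also make, by 165-fold (13.83 ± 0.12 against 6.46 ± 0.80), Esam by 32.2-fold, Kdr, which encodes VEGF receptor 2, by 4.24-fold (8.71 ± 0.89 against 6.63 ± 0.16, adjusted p = 0.00186), and Plvap, which encodes a protein of fenestrated endothelium (8.86 ± 0.50 against 5.28 ± 0.44). Whether Esam, Kdr or Plvap are also active in megakaryocytes was not tested. Clec14a was higher on the stromal arrays (9.70 ± 0.26 against 5.70 ± 0.42). Cdh5, which encodes VE-cadherin, and Emcn, which encodes endomucin, lay below the filter for dim genes and were not tested. Cdh5 stood at 5.39 ± 0.25 on the endothelial and 4.64 ± 0.13 on the stromal arrays, and Emcn at 4.14 ± 0.04 and 3.89 ± 0.35. Among 11 sinusoidal endothelial genes 2 were higher on the endothelial arrays, Lyve1 at -2.44 and Oit3 at -2.26, and 4 on the stromal arrays, including Adamts5 at 5.95. The median was -0.31, of other sign under another scaling, the mean 0.64 and the camera adjusted p 0.699. Stab2, a scavenger receptor gene of sinusoids, stood at -0.59 with an adjusted p of 0.0230 and did not reach the required difference. The arterial list had 4 of 10 members higher on the stromal arrays, including Fbln5 at 7.28, and none on the endothelial arrays (median -0.02, of other sign under another scaling, mean 1.33, adjusted p = 0.749). Of 18 endothelial transcription factors 9 were higher on the endothelial and 3 on the stromal arrays (adjusted p = 0.00196, and adjusted p = 0.177 with an estimated correlation). The former included Tal1 at -6.28, Lyl1 at -5.79, Hhex at -5.62 and Gata2 at -4.19, all of them also regulators of blood cell formation.

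Lists of several other blood lineages also shifted toward the endothelial arrays, while the plasma cell and the stem and progenitor lists, given further on, did not pass. Of 17 pan-leukocyte genes 16 were higher there (median -3.05, adjusted p = 4.77e-06, and adjusted p = 0.361 with an estimated correlation). Fermt3, which encodes the integrin activator kindlin-3, stood at 13.97 ± 0.20 against 7.32 ± 1.26, and Itgb2 at 12.40 ± 0.50 against 6.15 ± 1.48. The Fermt3 difference ranged from -7.08 to -2.55 over the alternatives. Whether genes of these blood lineage lists are also active in megakaryocytes was not tested. The B-lineage list had 11 of 13 members higher (adjusted p = 0.00196, and adjusted p = 0.438 with an estimated correlation), with Cd37 at -2.94. That list's mean lay at 9.14 on endothelial 2 against 7.41 and 7.62 on endothelial 1 and 3, and at 5.91 to 6.77 on the stromal arrays. Cd79b lay at 11.44 on endothelial 2 against 7.97 and 9.46 on endothelial 1 and 3. Its difference was -3.53, and -1.88 with endothelial 1 alone against the stromal arrays. Neutrophil precursor genes were higher in 9 of 14 (adjusted p = 0.00569, and adjusted p = 0.468 with an estimated correlation), with Ctsg at -2.98. The populations overlapped in that list's mean, which lay at 10.40, 11.14 and 8.56 on endothelial 1 to 3 and at 8.87, 8.77, 7.02 and 7.60 on stromal 1 to 4. Monocyte and macrophage genes were higher in 9 of 14 and lower in 1, Cd14 (camera adjusted p = 0.00196, and adjusted p = 0.308 with an estimated correlation). The populations overlapped in Cd14. Its call was lost after both renormalizations, with treat, with the replicate block, with the hybridisation-control block and in 6 of the leave-one-out fits. Lyz2 stood at -4.29 and Fcer1g at -4.22. In the T and NK list 4 of 9 were higher (adjusted p = 0.00696, and adjusted p = 0.152 with an estimated correlation), with Nkg7 at -2.55. That call was lost after cyclic loess (adjusted p = 0.0639, in a range over the alternatives from 5.9e-05 to 0.152). In the erythroid list 4 of 9 were higher (adjusted p = 0.0287, and adjusted p = 0.468 with an estimated correlation), led by Gata1, a regulator of red cells and megakaryocytes, at -5.76. The erythroid call was lost without endothelial 1 (median -0.80, adjusted p = 0.149) and with no filter on dim genes (median -1.37, adjusted p = 0.0523, in a range over the alternatives from 0.00106 to 0.468). Cell cycle genes were higher in 12 of 21 (adjusted p = 0.00316, and adjusted p = 0.443 with an estimated correlation), with Mki67 at -2.72 and Ccna2 at -2.56. MHC class II genes were higher in 4 of 6 (adjusted p = 0.0166, and adjusted p = 0.372 with an estimated correlation), with H2-DMa at -2.71. With endothelial 1 alone against the stromal arrays the class II median was -1.13, with an adjusted p of 0.0756 within the 5 arrays and 0.0693 with the block. Without cross-hybridising probe sets the median was -1.22 and the adjusted p 0.132, in a range over the alternatives from 0.00243 to 0.372.

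**Figure D2:**
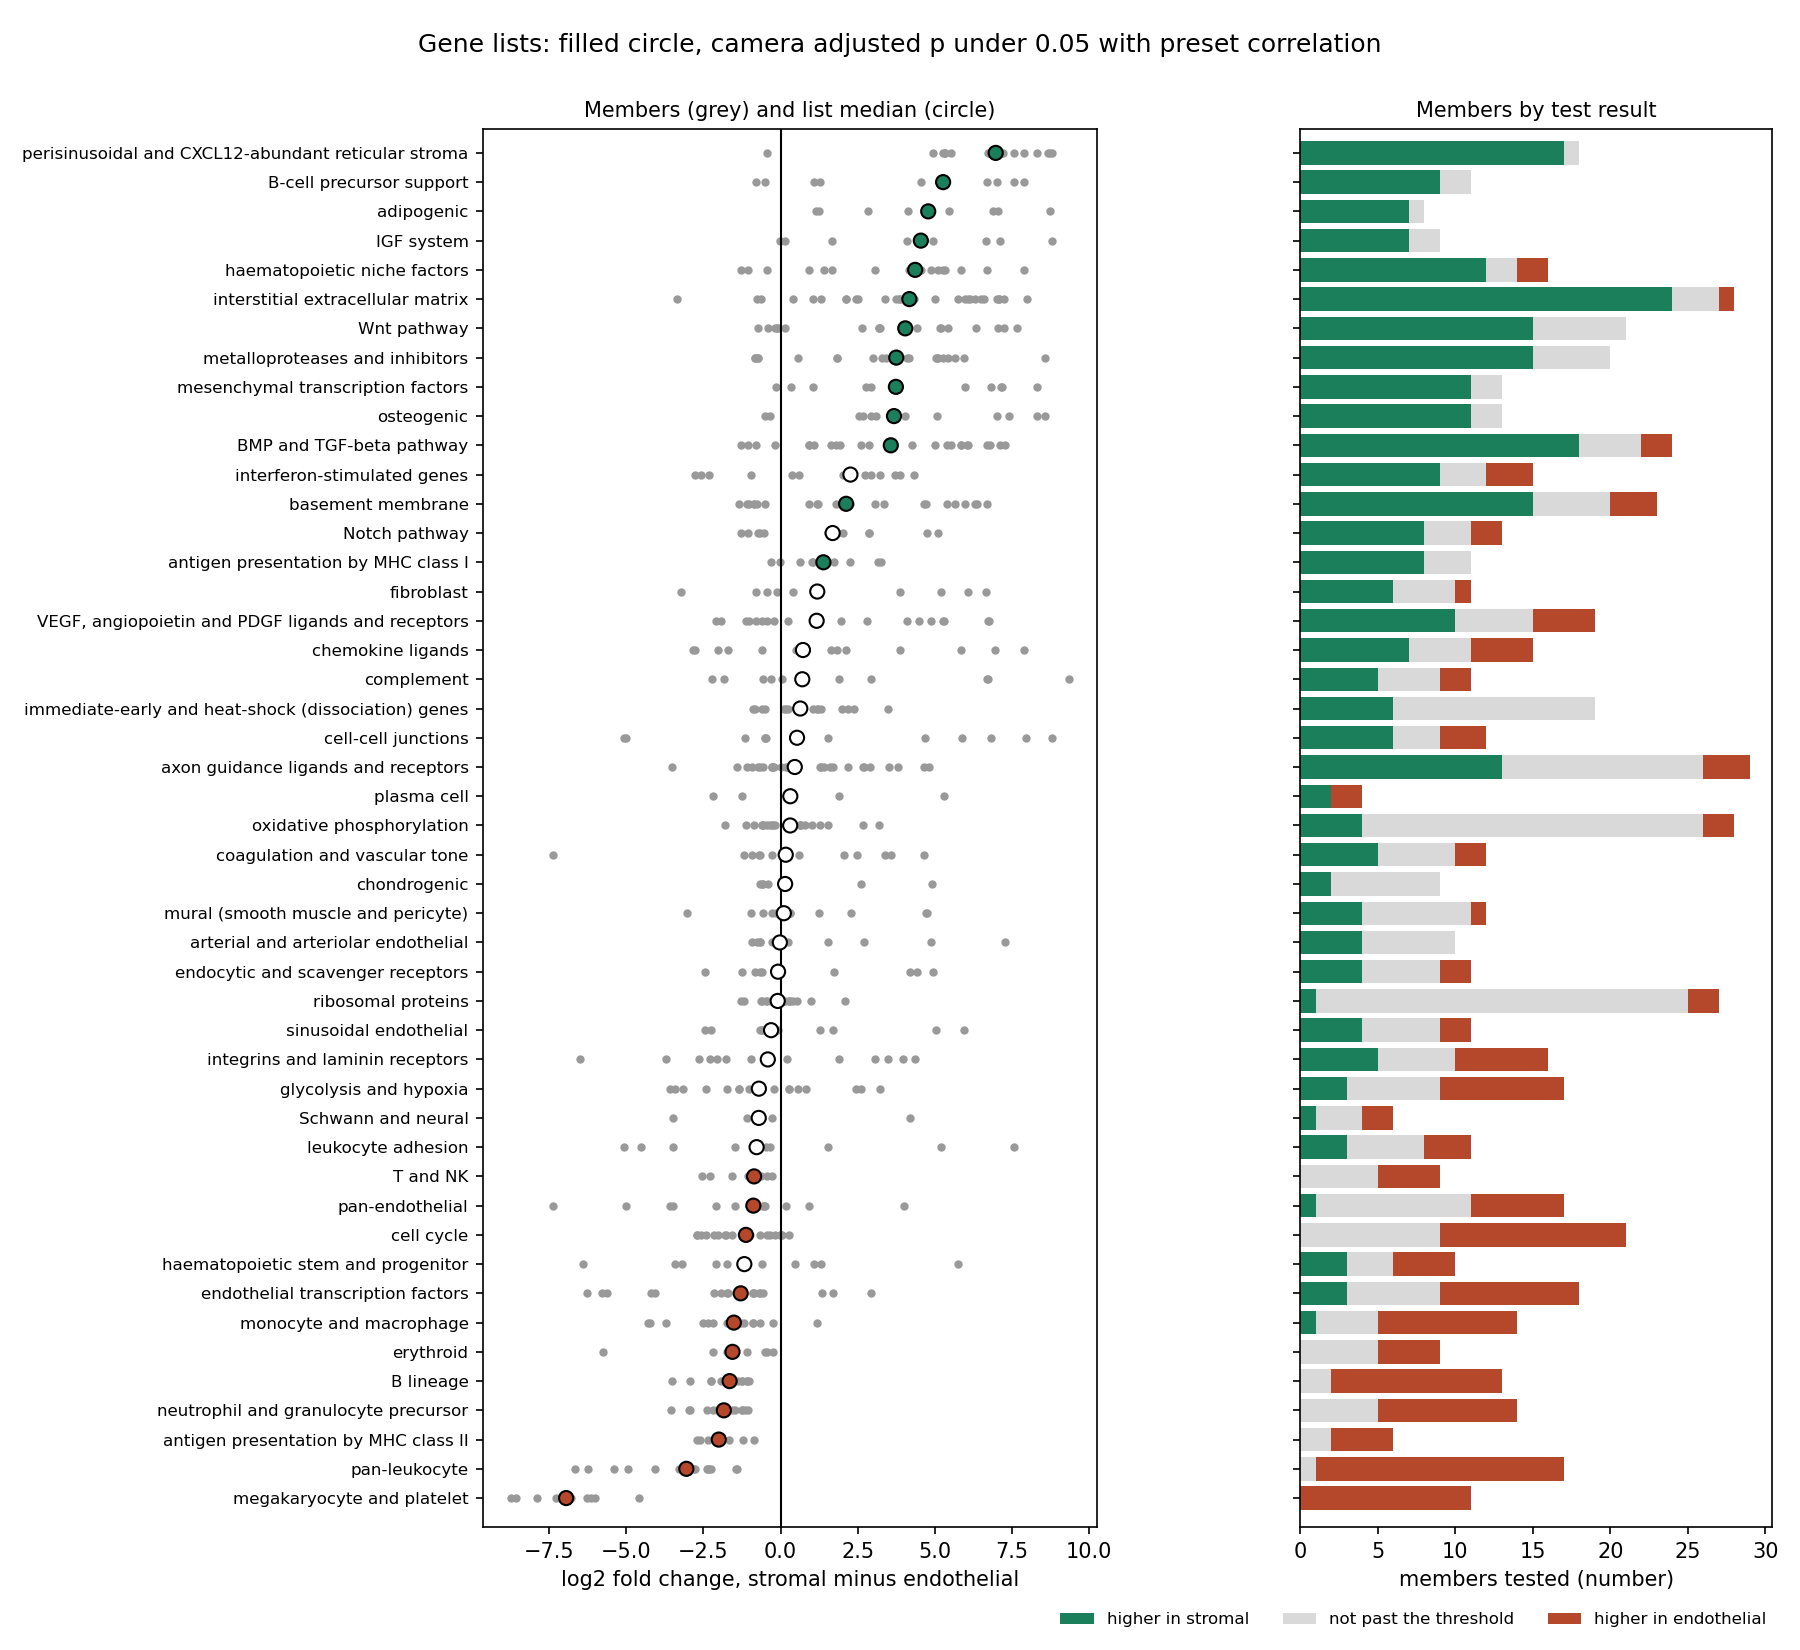
The 47 gene lists in order of median, with the tested members' log2 differences (stromal minus endothelial) as grey points, list medians as circles (filled where camera with preset correlation passed) and, at right, bars that count members higher on the stromal arrays (green), on the endothelial arrays (red) or on neither (grey). The medians run from -6.95 for the megakaryocyte and platelet list to 6.97 for the reticular stroma list.

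The other lists passed no camera test, with adjusted p values from 0.0681 to 0.975, and held members of both directions in most cases. Of 15 chemokine ligand genes 7 were higher on the stromal arrays, including the interferon-induced Cxcl9 at 6.95, and 4 on the endothelial arrays, including Ccl3 at -2.84. Of 16 integrin and laminin receptor genes 5 were higher on the stromal arrays, such as Itga1 at 4.35, and 6 on the endothelial arrays, such as Itga6 at -6.51 and Itgb3, a subunit of the platelet fibrinogen receptor, at -3.72. The VEGF, angiopoietin and PDGF list split 10 to 4 of 19, with Pdgfra at 6.74 and Pdgfa at -1.95. The Notch list split 8 to 2 of 13, with Jag1 at 5.09, and the axon guidance list 13 to 3 of 29, with Slit2 at 4.80 and Plxna4 at -3.52. Of 12 junction genes 6 were higher on the stromal arrays, led by the cadherin genes Cdh2 and Cdh11 at 8.79 and 7.97, and 3 on the endothelial arrays, among them F11r at -5.08. Leukocyte adhesion genes split 3 to 3 of 11, with Selp, which encodes P-selectin, at -4.53. Of 15 interferon-stimulated genes 9 were higher on the stromal arrays, such as Gbp2 at 4.34, and 3 on the endothelial arrays, among them Ifit2 at -2.77 and Rsad2 at -2.58 (adjusted p = 0.197, and 0.0429 with no filter on dim genes). Of 11 complement genes 5 were higher on the stromal arrays, with the C1 inhibitor gene Serping1 at 9.34 and C1ra at 6.69, and 2 on the endothelial arrays. The coagulation and vascular tone list split 5 to 2 of 12, with Thbd, which encodes thrombomodulin, at 3.40. The endocytic and scavenger list split 4 to 2 of 11 (median -0.08, mean 0.86), with Lrp1 at 4.44.

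Among markers of further cell types, the fibroblast list split 6 to 1 of 11, with Fap at 6.66 (7.71 without endothelial 2) and S100a4 at -3.22. The mural list split 4 to 1 of 12, with Notch3 at 4.76 and Myl9 at -3.04, and its median of 0.11 changed sign under another scaling. Of 9 chondrogenic genes 2 were higher on the stromal arrays, Comp at 4.92 and Col11a1 at 2.60 (list median 0.15, while the camera test pointed the other way with an adjusted p of 0.975). The Schwann and neural list split 1 to 2 of 6, with S100b at 4.19 and Mbp at -3.48. Of 4 plasma cell genes 2 were higher on each side, with Sdc1 at 5.30 and Mzb1 at -2.20 (adjusted p = 0.251 with the hybridisation-control block). The stem and progenitor list split 3 to 4 of 10, with Hoxa9 at 5.76 on one side and Slamf1, also a megakaryocyte antigen, at -6.42 on the other. In housekeeping processes most members passed neither way, namely 22 of 28 oxidative phosphorylation genes and 24 of 27 ribosomal protein genes. The latter include Mrpl23, a mitochondrial ribosomal protein gene that a synonym matched to Rpl23, and without it the count is 23 of 26. Oxidative phosphorylation split 4 to 2 and the ribosomal proteins 1 to 2. Glycolysis and hypoxia genes split 3 to 8 of 17 (adjusted p = 0.0681), with Pkm at -3.43 and Hk1 at -3.17. The list passed without endothelial 3 (adjusted p = 0.0338), with a filter at the 60th percentile and after cyclic loess, in a range over the alternatives from 6.41e-04 to 0.537. With endothelial 1 alone against the stromal arrays it passed with the block (adjusted p = 0.0209) and not within the 5 arrays (adjusted p = 0.129). Of 19 immediate-early and heat-shock genes, which respond to tissue dissociation, 6 were higher on the stromal arrays and none on the endothelial arrays, with Socs3 at 3.49 and Egr1 at 2.38.

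In total 13 of the 47 lists shifted toward the stromal arrays and 11 toward the endothelial arrays by camera with a preset correlation of 0.01. Some genes stand in several lists (863 entries, 783 distinct genes), such as Il7, Cxcl12 and Kitl in the niche factor and B-cell precursor lists. These calls are therefore not independent. With an estimated correlation camera called 0 lists after adjustment, with 13 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0818, and fry, which asks only whether a list's genes move one way, passed 42. Camera with an estimated correlation also bounds its degrees of freedom by the number of arrays. Calls lost under it, here and above, therefore need not come from gene correlation alone. Counts of members adjusted over the list alone differed from those above in 4 lists: MHC class II 5 instead of 4, cell cycle 11 instead of 12, ribosomal proteins 0 instead of 2 on the endothelial arrays, and immediate-early genes 5 instead of 6.

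The arrays separated by population before any test. Correlations across probe sets, which are not independent replicates, lay between 0.968 and 0.986 among the stromal arrays and between 0.902 and 0.931 among the endothelial arrays. Between the populations they lay between 0.708 and 0.80. The first principal component held 84.7% of the variance and placed all 4 stromal arrays on one side and all 3 endothelial arrays on the other. The 27 bacterial poly-A control probe sets averaged 3.61 to 3.73 on the stromal arrays and 3.99 to 4.29 on the endothelial arrays. The 4198 genes below the filter had a median difference of -0.58. The 3' minus 5' difference of a control transcript can reflect both RNA integrity and the amplification, and does not tell them apart. For Gapdh it was 3.26 ± 0.19 (SD, n = 4) on the stromal arrays and 2.80 ± 0.61 (SD, n = 3) on the endothelial arrays. These means differed by 0.46, with an exact two-sided permutation p of 0.20. For Actb the 3' minus 5' difference was 1.51 ± 0.24 (n = 4) against 1.03 ± 0.42 (n = 3), with an exact two-sided permutation p of 0.143. The smallest p the 35 arrangements allow is 0.0286.

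**Figure D3:**
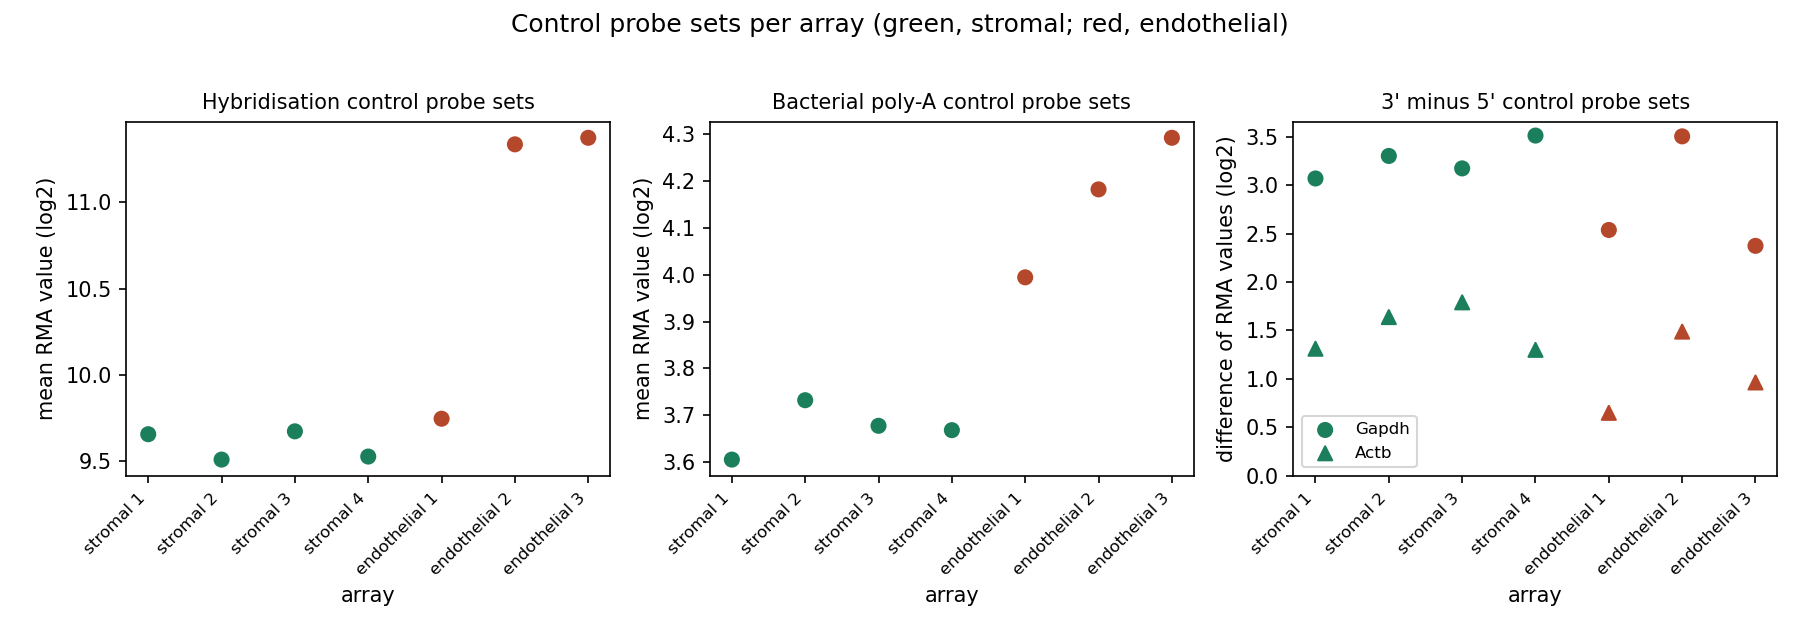
Control probe sets on each of the 7 arrays, as the mean log2 value of the hybridisation (left) and bacterial poly-A (middle) controls and the 3' minus 5' log2 difference of Gapdh (circles) and Actb (triangles). The hybridisation controls lie at 11.33 and 11.37 on endothelial 2 and 3 and between 9.51 and 9.75 on the other 5 arrays, and the left and middle axes do not start at 0.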

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

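The tests of swapped labels, of mostly endothelial cells, of the further megakaryocyte list, of carry-over from all blood cells, of the array floor and of the hybridisation-control split were chosen only after the results were seen.

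On the arrays labelled endothelial, megakaryocyte and platelet genes were raised throughout, while Cdh5 and Emcn lay below the filter, and a swap of the labels is excluded, since Enpep was higher on the stromal arrays by 6.93. The median difference of the 23 pan-endothelial genes was -0.84 (95% bootstrap interval over the genes, -1.0 to -0.58). Of these genes 6 lay below the filter and 1 was higher on the stromal arrays. Another 6 were higher on the endothelial arrays past the threshold, among them Kdr, Plvap, Esam and Vwf. A median of -3 or lower was required for mostly endothelial cells with some platelet RNA. That bound was set after the results were seen, and the interval measures the spread over genes, not samples. The test therefore does not decide whether the sort held mostly endothelial cells. This test replaced an earlier version on percentiles within an array (57.9 to 62.3 on the 3 arrays, against bounds of 80 and 60), which was dropped after its value fell between its bounds, because it set different probe sets against each other. Megakaryocyte-lineage cells in the sort may account for the pattern, although the gates excluded CD45-positive and lineage-positive cells: of 22 further megakaryocyte genes, 3 of them also in lists already tested, 21 were higher there and 19 past the threshold (median -3.19), which shows their RNA but not the share of such cells. The share of 63.6% that were higher and above the 90th percentile (14 genes, 13 of them past the threshold, against bounds of 70% and 40%) sets different probe sets against each other too and decides nothing, so this stays open, as does a biological difference between the sorted populations, which was not tested.

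Platelet genes were raised in stromal 4 above the other 3 stromal arrays, with the megakaryocyte list's mean at 8.40 against 6.56, 6.06 and 5.76. Carry-over of all blood cells stays open, since the pan-leukocyte list's mean lay at -0.21 relative to the other 3 arrays, whose SD was 0.978. RNA of the CD54-negative, CD31-positive cells in that sample could be a source: the 100 genes highest on the endothelial arrays and dim on the other stromal arrays had a median excess of 0.33 in stromal 4 (-0.11, 0.13 and -0.25 in stromal 1 to 3), with 17 of 100 above 1. That value lies between the bounds of 0.5 and 0.2 set for it, so the source is open.

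Dim genes were higher on the endothelial arrays, with a median of -0.58 over the 4198 genes below the filter, 93.5% of them lower on the stromal arrays. The bacterial control probe sets, which have no mouse target, moved alike with a median of -0.48, so the floor of the arrays may account for it, from background or normalization. Whether the hybridisation-control split is the whole cause stays open: endothelial 1, the only endothelial array outside it, lay 0.28 above the stromal mean in the bacterial controls (quartiles 0.14 and 0.50), and 1 array does not decide it. Among the genes called higher on the endothelial arrays, 118 lay below the 60th percentile on all 3 of them and 1153 differed by under 1.5, so calls of that kind are open to the same shift. List calls with small medians are open to it too, such as pan-endothelial at -0.88 and T and NK at -0.86.

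Of the 35 splits of the 7 arrays into 4 and 3, 1 gave as many called genes in limma, the real split with 6571. The highest other split gave 0, and 0 at adjusted p alone. At an unadjusted p under 0.05 and a log2 difference of at least 1, the highest other split gave 3668 against 6664. Splits that mix the populations carry their difference in the residual spread, so low counts there were built in. The smallest share these splits allow is 1 of 35, and the count of genes does not exclude chance. For the number of lists, 4 of the 35 splits gave as many, with 24 in the real split and 25 in the highest other. The others each kept 3 of the 4 stromal arrays together, so part of the real difference stayed in them. The count of lists therefore decides nothing about chance.

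Among the 4 stromal arrays, the gap of the highest or lowest array to the nearest other exceeded Dixon's 95% critical share of the range for 18 of 228 named genes and 1 of 47 list means, and chance gives about 1 in 20. Stromal 4 was the highest array for Efemp1 (0.892), Ephb4 (0.911), Gad1 (0.860), Hoxa9 (0.986), Icam1 (0.938), Ppbp (0.914), Tubb1 (0.907), Vwf (0.888) and the mean of the cell-cell junction list (0.919). It was the lowest for Jun (0.85), Ndufv1 (0.842) and S100b (0.924). Stromal 3 was the lowest for Gata2 (0.915), Itgb2 (0.836) and Lum (0.871), stromal 2 for Pdgfrb (0.913) and stromal 1 for Sptb (0.863). Stromal 1 was the highest for Cd3d (0.935) and Cxcl12 (0.840).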

How the results depend on the processing

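The hybridisation-control block and the fit within 5 arrays, which both compare endothelial 1 alone with the stromal arrays, the fit without stromal 4 and endothelial 2, and the ribosomal list without Mrpl23 were chosen after seeing the data. Over all alternatives, named genes kept direction and side of the threshold in 4736 comparisons, lost the call in 192, gained it in 1 and reversed in 2. List results kept theirs in 1024, lost in 34, gained in 21 and reversed in 2. Most named genes were picked for large differences in these same data, so their kept calls are partly built in. Both hybridisation-control fits are counted, although they are the same single check. Counts (within 1.5 times) and RNA quality values (within 1 SD) held in 100 and moved in 8. With treat, which tests against a log2 difference of 1, the counts were 2220 higher on the stromal and 855 on the endothelial arrays. With adjusted p alone 4412 were higher on the endothelial arrays, and per probe set the counts of genes higher in stromal cells and genes higher in endothelial cells became 7649 and 4293 probe sets. These follow from stricter, looser or larger families of tests. Camera with an estimated correlation called 0 lists toward the stromal and 0 toward the endothelial arrays, with 13 lists at an unadjusted p under 0.05, while fry called 27 toward the stromal and 15 toward the endothelial arrays. Rps24 reversed to 3.16 without cross-hybridising probe sets and Tap1 to -0.0145 with the mean of its probe sets, where the genes' probe sets disagree. Fry pointed toward the stromal arrays and camera the other way for the chondrogenic list (median 0.15) and the endocytic and scavenger list (median -0.0819). They also parted for the integrin and laminin receptor list (median -0.41), which passed neither (fry adjusted p = 0.193, camera adjusted p = 0.441). Camera compares a list with the other genes tested, and fry does not. The cause was not tested. Leaving out 1 array in turn gave 3980 to 4837 genes higher on the stromal and 2015 to 2643 on the endothelial arrays. With replicate number as a block they were 4176 and 2278. Signal near the floor of the arrays limits small differences among dim genes.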

Other observations

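In total 4 further gene lists, chosen after the data were seen, were tested together with camera. Receptors for cytokines and hormones were higher on the stromal arrays in 19 of 28 members and on the endothelial arrays in 2 (median 2.53, adjusted p = 5.12e-05, and adjusted p = 0.164 with an estimated correlation). They included Lifr at 8.42 and, named after their values were seen, the growth hormone receptor gene Ghr at 6.89, the oncostatin M receptor gene Osmr at 6.38 and Pth1r, which encodes the parathyroid hormone receptor, at 5.06. Csf2rb, which encodes a receptor chain for myeloid growth factors, stood at -2.45. Lipid-handling genes split 9 to 5 of 21 (adjusted p = 0.452), with Lpl at 7.04 (6.25 to 7.86 over the alternatives) and Apoe at 6.87 (6.50 to 7.50) on one side and Alox12 at -8.22 (-8.98 to -7.72) on the other. Receptors for nerve-derived signals split 2 to 2 of 11 (adjusted p = 0.373), with Ret at 2.51 and Ramp1 at -2.81.

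The further megakaryocyte list had 19 of 22 members higher on the endothelial arrays (median -3.19, adjusted p = 3.03e-10, and adjusted p = 0.0651 with an estimated correlation). Among them, named after their values were seen, were the platelet ADP receptor gene P2ry12, at 10.12 against 3.81 on the stromal arrays, and the thromboxane synthase gene Tbxas1, at 11.63 against 6.01. Of 4257 tested probe sets without a gene symbol, 632 were higher on the stromal and 517 on the endothelial arrays.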
